A study of Homo sapiens with 16 samples.

How the data were processed

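Gene expression was measured in SKGT4, an established human cell line from an oesophageal adenocarcinoma that arose with Barrett's oesophagus, on 16 Affymetrix arrays. The labels give 8 groups of 2 arrays. Cells were exposed to deoxycholic acid (DCA, a secondary bile acid) at 300 µM for 4, 8, 12 or 24 h, and resting cells were taken at the same times. Each array entered its group by its title, and none was left out. The title of a 12 h resting array spells the cell line with a different letter, while its source label names SKGT4 like all others. Per the labels' protocols, the DCA was given in RPMI medium without fetal calf serum or supplement, whereas growth medium held both and the resting cells were kept in untreated medium. The labels do not say whether the resting medium also lacked serum, so DCA and the absence of serum cannot be told apart in these groups.

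The authors deposited 1 table with an intensity value per probe set and array on a linear scale. The values came from MAS5, per the submitters' processing notes, which combines the perfect-match and mismatch probes of a probe set into an intensity and scales the arrays. The MAS5 version and target are not given in the sources used here, and neither detection calls nor scanner files were used here. The table held 54675 probe sets, of which 41097 had 1 gene symbol, 1801 several and 11777 none in the annotation used here. Symbols of 41043 probe sets were updated by gene ID. Probe sets with several symbols or none were not named or tested, and no column of the table lacked a sample.

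The 2% trimmed means of 9 arrays lay within 5% of the median trimmed mean of 99.99 units. Those of the other 7 arrays ranged from 37.6 to 191.5, and these 7 were all from 4 and 8 h. Because the deposited intensities were thus not on a common scale, every array was multiplied to the common median. A pseudocount of 4 (the 20th percentile of the table) was added and log2 was taken, which understates the change of dim genes. Each of 19775 genes was represented by its probe set with the highest mean. Genes whose mean intensity was at or below 13.1, the 40th percentile of all probe sets, were left out, and 14509 genes were tested.

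The model was limma (version 3.58.1, R 4.3.3) with lmFit and eBayes with an intensity trend, fitted to the means of the 8 groups, which shared a common estimate of the spread with 8 residual and 7.87 prior degrees of freedom. Contrasts were DCA minus resting at each time, the mean of these 4 differences, an F test of whether the difference changed over time, and an F test of the resting cells over time. For both F tests the direction given is the value at 24 h minus that at 4 h. List counts and list tests for these questions used the contrast of 24 h minus 4 h alone. A gene is called where the Benjamini-Hochberg adjusted p over all genes tested was below 0.05. The SE printed with a log2 change comes from this fit, with 2 arrays per side at a time and 8 per side in the mean. It does not follow the spread of each group, and the replicate SD ran from 0.317 for resting cells at 24 h to 0.535 for DCA at 12 h. Nothing in the labels says that arrays of a group came from separate cultures, although the design text speaks of duplicate experiments, so p-values measure the spread between these arrays, which may be technical. With 2 arrays per group, their number limits the precision.

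Before the data were examined, 31 gene lists were fixed: ATF4 and integrated stress, ER chaperones, tRNA synthetases, NF-κB, immediate early, EGFR and ERK output, NRF2, heat shock, metallothioneins, p53, BCL2 family and IAPs, sterol synthesis, fatty acid synthesis, bile acid handling, intestinal and Barrett markers, squamous markers, mitosis, S phase, FOXO, YAP and SRF targets, hypoxia and glycolysis, interferon response, autophagy and lysosome, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, EMT, WNT targets, and markers of fibroblasts, leukocytes and endothelium. Of these, 30 had the minimum of 5 members tested, and the endothelial list did not. Counts of members given below are of those tested. These were 12 of 24 for bile acid handling, 17 of 32 for intestinal and Barrett markers and 9 of 18 for squamous markers. They were 8 of 15 for WNT targets and 15 of 26 for ribosomal proteins. Lists were tested with camera (preset correlation 0.01, adjusted over lists), which compares a list with all other genes, and again with a correlation estimated from the data.

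The genes named were fixed by a rule at the same time. From the mean of the times it took the 12 largest rises and 12 largest falls among genes called and changed alike in all 8 same-numbered differences. Each time gave the 6 largest of each direction, with the same condition on its same-numbered differences, and each F test gave the 6 largest of each direction. Each list gave its 4 members with the largest absolute change among those called or, where fewer than 2 were called, the 2 with the smallest p. TRIB3 and CXCL8 were taken in every comparison, since published work on DCA in oesophageal cells is about them. Members named beyond this rule were chosen after their values were seen.

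The fit and the calling of genes were tested on simulated log2 values with independent noise, in which 200 of 14509 genes were changed. Array scaling, pseudocount, filter and choice of probe set were not part of this test. The share changed was far below the 51.5% called in the real data, and arrays shared no deviations, so the results may not carry over. For the mean of the times the fit recovered 49.3%, 80.6% and 97.0% of genes changed by 0.5, 1 and 2 on the log2 scale, with 8 false calls. At 4 h the shares were 10.4%, 56.7% and 80.3%, with 4 false calls. At 8 h they were 13.4%, 70.1% and 75.8%, with 7 false calls, and at 12 h 8.96%, 43.3% and 78.8%, with 0. At 24 h they were 13.4%, 58.2% and 74.2%, with 2 false calls. For the change of the DCA effect over time they were 0%, 38.8% and 69.7%, with 7 false calls, and for resting cells 7.46%, 49.3% and 83.3%, with 3.

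Alternatives fixed at the start were quantile normalization, median centring of each array, other pseudocounts, other low-value filters, the mean of all probe sets of a gene, no intensity trend, the replicate number as a block, each time fitted alone, an estimated list correlation, and leaving out each array in turn. Another pseudocount, fits of part of the times, and 2 further lists were added after the data were seen. Their effects stand in the closing section.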

Results

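The data are the signal of 14509 genes on 16 arrays of SKGT4 cells, 8 after exposure to 300 µM DCA and 8 from resting cells, with 2 arrays of each kind at 4, 8, 12 and 24 h. DCA is a bile acid made by gut bacteria and is a component of the fluid that refluxes into the oesophagus. The labels give the resting cells as controls matched in time, so the main question was which transcripts differed between exposed and resting cells at each time. A second question was how that difference changed over the hours. Arrays of the same group correlated with r from 0.939 to 0.977 across genes, and the pooled replicate SD of a group lay between 0.317 and 0.535 on the log2 scale. In what follows, "rose" and "fell" refer to DCA minus time-matched resting cells unless resting cells are named, and changes are given on the log2(signal + 4) scale with the SE of the fit. The DCA medium lacked serum per the labels, and whether the resting medium did is not stated, so each difference belongs to DCA and its medium together.

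Over the mean of the 4 times, the 12 largest rises included PTGS2, DUSP1, ATF3 and CHAC1, and the 12 largest falls included UHRF1, LFNG and SOX2. PTGS2, the inducible cyclooxygenase, rose by 4.90 (SE 0.07, n = 8 arrays per side, limma adjusted p = 5.83e-17). It was followed by C11orf96 (4.42, SE 0.27), the stress transcription factor ATF3 (4.35, SE 0.09) and the MAP kinase phosphatase DUSP1 (4.20, SE 0.08). ESM1 (3.79, SE 0.14), the glutathione-degrading enzyme CHAC1 (3.75, SE 0.09), the cytokine IL11 (3.53, SE 0.17), KRT16 (3.52, SE 0.18) and the IL-33 receptor IL1RL1 (3.50, SE 0.05) also rose, as did the transcription factor EGR1 (3.44, SE 0.13), SESN2 (3.25, SE 0.08) and DUSP5 (3.22, SE 0.08). The largest falls were LFNG, a glycosyltransferase that modifies Notch receptors (-4.14, SE 0.29), ZNF488 (-3.91, SE 0.20) and UHRF1, which maintains DNA methylation at replication (-3.28, SE 0.11). RERG (-3.22, SE 0.18), the integrin ITGB8 (-3.17, SE 0.16), CAVIN2 (-3.16, SE 0.19), the chemokine CXCL6 (-2.98, SE 0.09) and the death ligand TNFSF10 (-2.97, SE 0.07) followed. ASB2 (-2.96, SE 0.29), the transcription factor SOX2 (-2.94, SE 0.06), the BMP inhibitor SMAD6 (-2.92, SE 0.24) and the non-coding MIR181A2HG (-2.80, SE 0.30) completed the set. Some signals lay at or below the low-value limit of 13.1 units in at least 1 DCA group (LFNG, ZNF488, RERG, CAVIN2, ASB2, SMAD6, MIR181A2HG) or resting group (C11orf96). The sizes of these changes and their order are therefore uncertain, here and for genes so named below.

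In all, limma called 7472 of 14509 genes (51.5%) in the mean of the times, 2857 higher and 4615 lower with DCA, and 512 of the higher and 995 of the lower ones changed at least 2-fold. The share of higher genes among those called was 38.24% with the scaling used and 56.49% with each array centred on its median. Centring moved the median change of all genes from -0.07 to 0.11, so the balance of rises and falls and any change of that size depend on the scaling. Of the 30 lists tested with camera, 18 were called, 14 up and 4 down, and 13 of them with an estimated correlation.

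The ATF4 list, whose genes are induced when amino acid supply or protein folding is disturbed, had the largest median rise of the lists. Of its 30 members, 25 rose, 0 fell and 5 did not pass (26 rose when adjusted over the list alone). ATF3 and CHAC1 led it, followed by SESN2 and by DDIT3, which encodes the pro-apoptotic factor CHOP (3.20, SE 0.06). The median was 1.79 (SD over members 1.03, camera adjusted p = 1.4e-23, and adjusted p = 7.49e-05 with an estimated correlation). Aminoacyl-tRNA synthetases, several of which are ATF4 targets, moved both ways: 10 of 17 rose and 4 fell (the same counts adjusted over the list alone). GARS1 rose by 1.96 (SE 0.06), WARS1 by 1.94 (SE 0.05), YARS1 by 1.65 (SE 0.07) and CARS1 by 1.58 (SE 0.06), whereas FARSA, which encodes a subunit of the phenylalanine enzyme, changed by -0.79 (SE 0.09). The list was called up (median 0.68, camera adjusted p = 3.57e-05, and 0.0189 as adjusted p with an estimated correlation).

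Genes of the endoplasmic reticulum also rose. Of 24 chaperone and degradation genes, 18 rose and 1, CRELD2 (-0.48, SE 0.05), fell, both over all genes and adjusted over the list alone. DNAJB9, a co-chaperone of BiP (2.80, SE 0.06), the transcription factor XBP1 (2.12, SE 0.06), HERPUD1 (1.67, SE 0.06) and the vesicle coat gene SEC24D (1.56, SE 0.10) rose most, while HSPA5, which encodes BiP itself, rose by 0.89 (SE 0.05). The median was 0.44 (camera adjusted p = 8.19e-08, and adjusted p = 0.0302 with an estimated correlation). Autophagy and lysosome genes rose in 13 of 22 cases and fell in 3 (the same adjusted over the list alone), with MAP1LC3B at 2.04 (SE 0.06), ULK1 at 1.94 (SE 0.12), WIPI1 at 1.65 (SE 0.06) and GABARAPL1 at 1.47 (SE 0.07). The list had a median of 0.26 and a camera adjusted p of 0.000236 (adjusted p = 0.0132 with an estimated correlation). Of its lysosomal members, CTSB, LAMP1 and LAMP2 had changes of -0.03, 0.08 and -0.06, none of which passed. They were picked after their values were seen and do not stand for the lysosomal part, since other lysosomal members were among those called.

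Oxidative stress genes rose, and heat shock genes did not move as a group. Of 21 NRF2 targets, 17 rose and 2 fell, both over all genes and adjusted over the list alone (median 0.28, camera adjusted p = 2.4e-06, and adjusted p = 0.0275 with an estimated correlation). The cystine transporter SLC7A11, which is also an ATF4 target, rose by 2.38 (SE 0.05), haem oxygenase HMOX1 by 2.01 (SE 0.09) and SRXN1 by 1.81 (SE 0.05), whereas the aldo-keto reductase AKR1B10 fell by 1.84 (SE 0.07). Metallothioneins and the zinc exporter SLC30A1 rose in 6 of 7 cases and fell in 0 (7 of 7 rose adjusted over the list alone). SLC30A1 rose by 1.24 (SE 0.06), MT1X by 0.50 (SE 0.07), MT1G by 0.39 (SE 0.05) and MT1H by 0.39 (SE 0.07). Another probe set of MT1X was called in the opposite direction. The list median was 0.39 (camera adjusted p = 0.000746, and adjusted p = 0.0189 with an estimated correlation). Among 14 heat shock genes 5 rose and 6 fell (5 and 7 adjusted over the list alone). HSPA4L changed by -1.04 (SE 0.15), the mitochondrial chaperonin HSPE1 by -0.88 (SE 0.06), STIP1 by -0.64 (SE 0.09) and DNAJB1 by 0.56 (SE 0.05). The list was not called (median -0.08, and 0.11 with median centring, camera adjusted p = 0.858).

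Inflammatory and growth factor programmes rose together. In the NF-κB list 14 of 24 genes rose and 4 fell (the same adjusted over the list alone, median 0.64, camera adjusted p = 6.32e-07, and adjusted p = 0.00371 with an estimated correlation). Besides PTGS2, IL1B rose by 2.19 (SE 0.06), LIF by 2.16 (SE 0.07) and IL1A by 2.11 (SE 0.06). The 4 that fell were the chemokines CXCL1 (-1.24, SE 0.05), CXCL3 (-0.38, SE 0.08) and CCL2 (-1.45, SE 0.31) and TNFAIP2 (-0.44, SE 0.05). Of 19 immediate early genes 15 rose and 1, JUN (-0.45, SE 0.08), fell, both over all genes and adjusted over the list alone. DUSP1 and DUSP5 led with EGR1 and with the transcription factor FOS (2.51, SE 0.26). The median was 1.51 (camera adjusted p = 6.75e-12, and adjusted p = 0.00371 with an estimated correlation). Of 18 genes that report EGFR and ERK activity, 13 rose and 2 fell (14 and 2 adjusted over the list alone). The EGFR ligand HBEGF rose by 2.88 (SE 0.09), and the ERK feedback inhibitors DUSP6 by 2.42 (SE 0.07) and SPRY4 by 2.12 (SE 0.10), with ETV5 at 1.91 (SE 0.06). CCND1 and EPHA4 fell. The median was 1.12 (camera adjusted p = 6.91e-09, and adjusted p = 0.0189 with an estimated correlation).

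Cell cycle genes fell. Every one of 26 S phase genes fell, over all genes and adjusted over the list alone, with UHRF1 followed by GINS1 (-2.18, SE 0.06), CCNE2 (-2.09, SE 0.11) and MCM10 (-2.08, SE 0.10), which serve origin firing and entry into S phase. The median was -1.50 (camera adjusted p = 2.36e-16, and adjusted p = 0.000739 with an estimated correlation). Of 23 mitosis genes 22 fell and 0 rose (23 fell adjusted over the list alone), among them the kinesins KIF20A (-1.81, SE 0.11) and KIF11 (-1.58, SE 0.09), the checkpoint kinase BUB1B (-1.23, SE 0.07) and FOXM1 (-1.07, SE 0.07). The median was -0.88 (camera adjusted p = 1.17e-10, and adjusted p = 0.000739 with an estimated correlation).

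**Figure D1:**
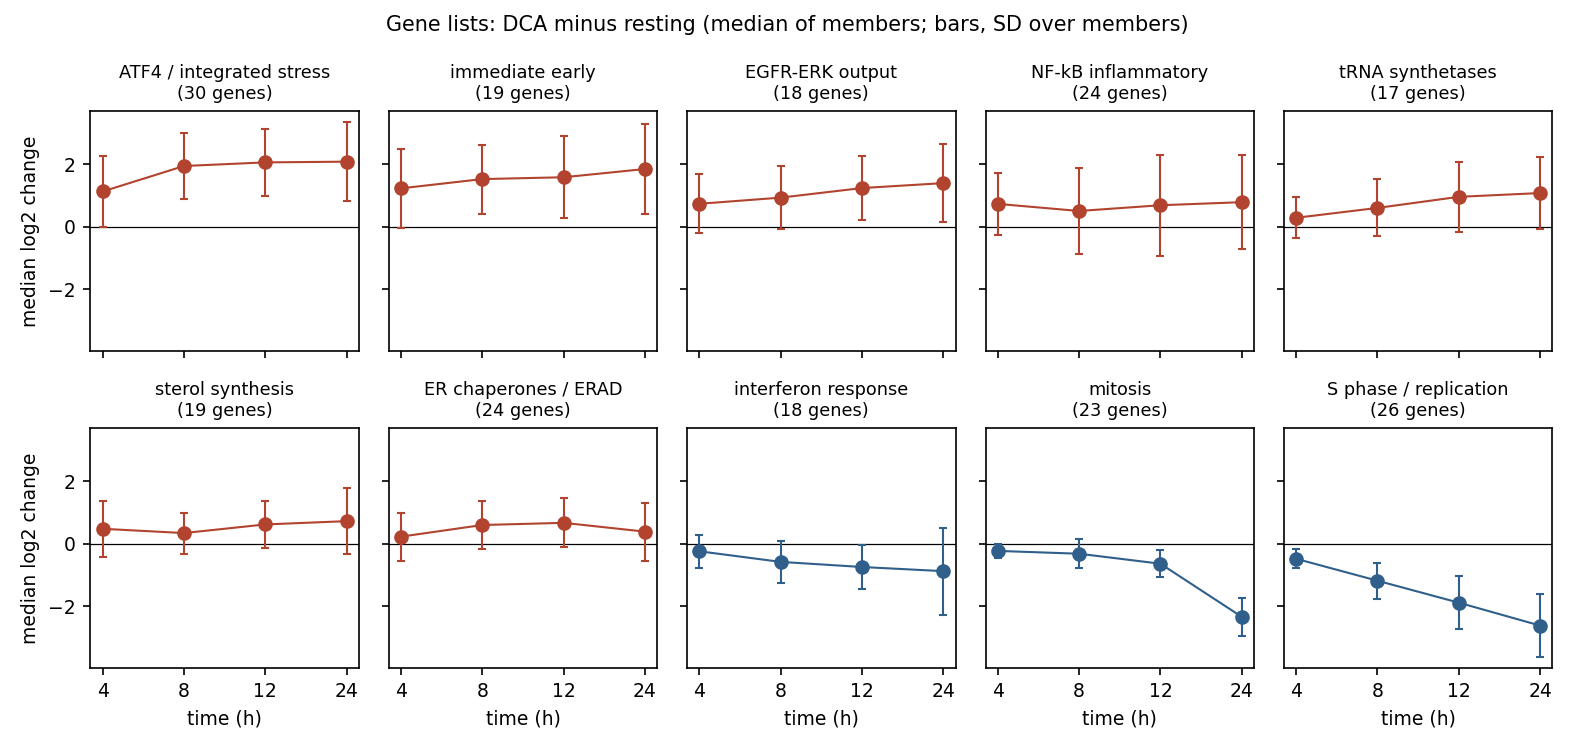
Median change of 10 gene lists, DCA minus resting, on a log2 scale against time of exposure in h (evenly spaced categories), with bars giving the SD over the list's members and the number of members in each title. The S phase median was -0.48 at 4 h and -2.62 at 24 h, and the mitosis median -0.23 at 4 h and -2.34 at 24 h.

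Death and growth arrest lists went both ways. Among 20 p53 targets 7 rose and 8 fell (the same adjusted over the list alone). GDF15 rose by 2.44 (SE 0.06), GADD45A by 1.71 (SE 0.06), PLK3 by 1.63 (SE 0.16) and the CDK inhibitor CDKN1A by 1.48 (SE 0.06), while the DNA repair gene DDB2 fell by 1.75 (SE 0.10) and FAS by 0.93 (SE 0.06). The list's median was -0.13, its mean 0.12 and its camera direction up, and it was not called (adjusted p = 0.675). Its median was 0.06 with median centring. Of 17 BCL2 family and IAP genes 7 rose and 5 fell (the same adjusted over the list alone, median 0.28, camera adjusted p = 0.313). The survival genes BCL2A1 (2.19, SE 0.23) and MCL1 (0.97, SE 0.05) and the pro-apoptotic PMAIP1 (0.91, SE 0.07) rose, and BIRC5, which also serves mitosis, fell by 1.31 (SE 0.06). FOXO targets, which rise on growth factor withdrawal, rose in 10 of 19 cases and fell in 5 (the same adjusted over the list alone). YPEL5 rose by 1.51 (SE 0.06), BTG1 by 1.496 (SE 0.09) and CCNG2 by 1.42 (SE 0.09), and SESN3 fell by 1.48 (SE 0.17). That list was called (median 0.55, camera adjusted p = 0.014), but not with an estimated correlation (adjusted p = 0.302 with an estimated correlation) nor with median centring (adjusted p = 0.0539).

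Sterol synthesis genes rose, and bile acid handling genes did not. Of 19 sterol genes 13 rose and 3 fell (13 and 4 adjusted over the list alone). The SREBP regulator INSIG1 rose by 1.67 (SE 0.09), MSMO1 by 1.36 (SE 0.08) and the cholesterol transfer gene STARD4 by 1.24 (SE 0.09), whereas the reductase TM7SF2 fell by 1.31 (SE 0.17). The median was 0.63 (camera adjusted p = 5.35e-05, and adjusted p = 0.0171 with an estimated correlation). Of 13 fatty acid genes 6 rose and 4 fell (7 and 4 adjusted over the list alone). ACSS2, which makes acetyl-CoA, rose by 1.92 (SE 0.08) and MID1IP1 by 0.85 (SE 0.11), and the values were -1.28 (SE 0.29) for ELOVL5 and -0.91 (SE 0.33) for PNPLA3. The list passed narrowly (median 0.53, camera adjusted p = 0.0416) and not with an estimated correlation (adjusted p = 0.185 with an estimated correlation). The call was also lost with quantile normalization (0.0665), median centring (0.0793), the mean of all probe sets (0.111), a pseudocount of 32 (0.0506), only the arrays of 12 and 24 h (0.154) and without the first DCA array of 4 h (0.0636). Of 12 bile acid handling genes 0 rose and 4 fell, both over all genes and adjusted over the list alone: CYP24A1, the vitamin D hydroxylase (-1.999, SE 0.14), the ileal bile acid binder FABP6 (-1.62, SE 0.28), CYP27A1 (-0.998, SE 0.37) and ABCC4 (-0.48, SE 0.09). This list was not called (median -0.21, camera adjusted p = 0.46).

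The intestinal and squamous marker lists were not called, and the EMT list was. Of 17 intestinal and Barrett genes 7 rose and 2 fell (8 and 2 adjusted over the list alone). The mucins MUC6 (0.84, SE 0.32) and MUC2 (0.72, SE 0.27) and the transcription factor GATA6 (0.61, SE 0.08) rose, and the goblet cell factor SPDEF fell by 0.83 (SE 0.31). MUC6 turned to -0.24 with only the arrays of 12 and 24 h, and 5 of its 8 same-numbered differences were rises. The list missed the threshold (median 0.35, camera adjusted p = 0.057). It was called without the second resting array of 12 h (0.0489) or without the first DCA array of 4 h (median 0.53, adjusted p = 0.0381), of 12 h (0.0373) or of 24 h (0.0462), and without all 12 h arrays (0.0473). Of 9 squamous genes 2 rose and 4 fell (3 and 4 adjusted over the list alone). KRT16, a keratin of stressed and wounded squamous epithelium, and SOX2 moved in opposite directions, and KRT13 (-1.45, SE 0.27) and S100A2 (-0.92, SE 0.05) fell. The list median was 0.02, its mean -0.13 and its camera direction down (adjusted p = 0.602). Of 14 EMT genes 8 rose and 5 fell (the same adjusted over the list alone). They included the epithelial junction gene OCLN (1.31, SE 0.10) and the mesenchymal factor ZEB1 (1.19, SE 0.07), both of which rose, and the proteases MMP1 (1.63, SE 0.07) and MMP7 (-1.31, SE 0.16). Because the list holds epithelial and mesenchymal genes together, its call gives no direction for EMT itself. The list was called up (median 0.28, camera adjusted p = 0.0385), but not with an estimated correlation (adjusted p = 0.0814 with an estimated correlation), with median centring (adjusted p = 0.0704), no filter (0.0716), only the arrays of 12 and 24 h (0.124), the first DCA array of 8 h left out (0.0505) or the replicate number as a block (adjusted p = 0.0525), and the intestinal list was called with that block (adjusted p = 0.0477).

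Interferon-stimulated genes fell. Of 18 members 13 fell and 2 rose (the same adjusted over the list alone). IFIT1 fell by 1.69 (SE 0.06), IFIT3 by 1.65 (SE 0.08), OAS1 by 1.41 (SE 0.10) and IFIT2 by 1.27 (SE 0.12), while the regulators IRF9 (0.92, SE 0.08) and IRF7 (0.51, SE 0.11) rose. The median was -0.49 (camera adjusted p = 0.00792, and adjusted p = 0.033 with an estimated correlation). Of 21 hypoxia and glycolysis genes 8 rose and 8 fell (the same adjusted over the list alone). NDRG1 (2.46, SE 0.05), SLC2A3 (1.96, SE 0.36) and VEGFA (1.66, SE 0.05) rose, and EGLN3 fell by 2.17 (SE 0.08). The list was not called (adjusted p = 0.41). Its median was -0.03, with a mean of 0.15 and an upward camera direction, and the median was 0.16 with median centring and 0.04 with quantile normalization. Of 15 YAP and SRF targets 5 rose and 6 fell (the same adjusted over the list alone), with LATS2 at 1.47 (SE 0.07), AMOTL2 at 1.39 (SE 0.10), THBS1 at -1.62 (SE 0.12) and MYL9 at -1.24 (SE 0.21). This list was not called either (median -0.14, and 0.04 with median centring, adjusted p = 0.995). Of 8 WNT targets 1, MYC (0.97, SE 0.06), rose and 3 fell (the same adjusted over the list alone), with DKK1 at -1.19 (SE 0.06), ZNRF3 at -1.08 (SE 0.08) and CCND1 at -0.57 (SE 0.06). Their median was -0.16, and 0.02 with median centring (adjusted p = 0.508).

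Genes of protein synthesis and respiration changed by amounts close to the shift between scalings. All 15 ribosomal protein genes rose, over all genes and adjusted over the list alone, by a median of 0.30 (camera adjusted p = 0.000153). The call was lost with an estimated correlation (adjusted p = 0.378 with an estimated correlation) and with quantile normalization (median 0.0003, adjusted p = 0.898). RPS19 had a value of 0.35 (SE 0.11), RPL19 of 0.33 (SE 0.06), RPS6 of 0.32 (SE 0.08) and RPL22 of 0.32 (SE 0.09), calls that quantile normalization ended. Ribosome biogenesis genes fell in 10 of 20 cases and rose in 1 (the same adjusted over the list alone), among them POLR1B (-0.82, SE 0.06), RRP9 (-0.68, SE 0.17), NHP2 (-0.64, SE 0.06) and NOP16 (-0.57, SE 0.06). That list was not called (median -0.19, adjusted p = 0.102), but was with quantile normalization (adjusted p = 0.0441), no filter (0.0307) and only the arrays of 12 and 24 h (0.00493). Of 24 genes of the respiratory chain 15 fell and 1 rose (17 and 1 adjusted over the list alone). NDUFV1 fell by 0.62 (SE 0.07), NDUFB8 by 0.61 (SE 0.06), NDUFB3 by 0.59 (SE 0.08) and NDUFA8 by 0.56 (SE 0.05), and another probe set of NDUFB8 was called in the opposite direction. The list was called (median -0.29, camera adjusted p = 0.000902), but not with an estimated correlation (adjusted p = 0.0814 with an estimated correlation) or with median centring (median -0.11, adjusted p = 0.0539).

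Markers of fibroblasts, leukocytes and endothelium fell or did not pass. Of 6 fibroblast genes 0 rose and 2 fell, COL1A2 (-0.72, SE 0.15) and COL1A1 (-0.31, SE 0.09), and of 8 leukocyte genes 0 rose and 3 fell, CD14 (-1.75, SE 0.42), CORO1A (-1.63, SE 0.13) and LAPTM5 (-0.51, SE 0.10). The counts were the same adjusted over each list alone. Neither list was called (medians -0.23 and -0.07, the latter 0.12 with median centring, camera adjusted p = 0.675 and 0.566). Of the 9 endothelial markers only 4 were tested, too few for a list test, and CDH5 (-2.37, SE 0.15) and PECAM1 (-0.32, SE 0.10) were the named ones. With median centring COL1A1 (-0.12) and PECAM1 (-0.14) lost their calls. Among the genes named so far, the calls of CYP27A1, SPDEF, PNPLA3, MUC2 and MUC6 were each lost in several alternatives, and ELOVL5, ABCC4, GATA6, MYL9, NOP16 and MT1X lost theirs with the mean of all probe sets. CD14 lost its call with only the arrays of 12 and 24 h (-1.63, adjusted p = 0.0658, against 0.000445 to 0.0658 over the alternatives).

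**Figure D2:**
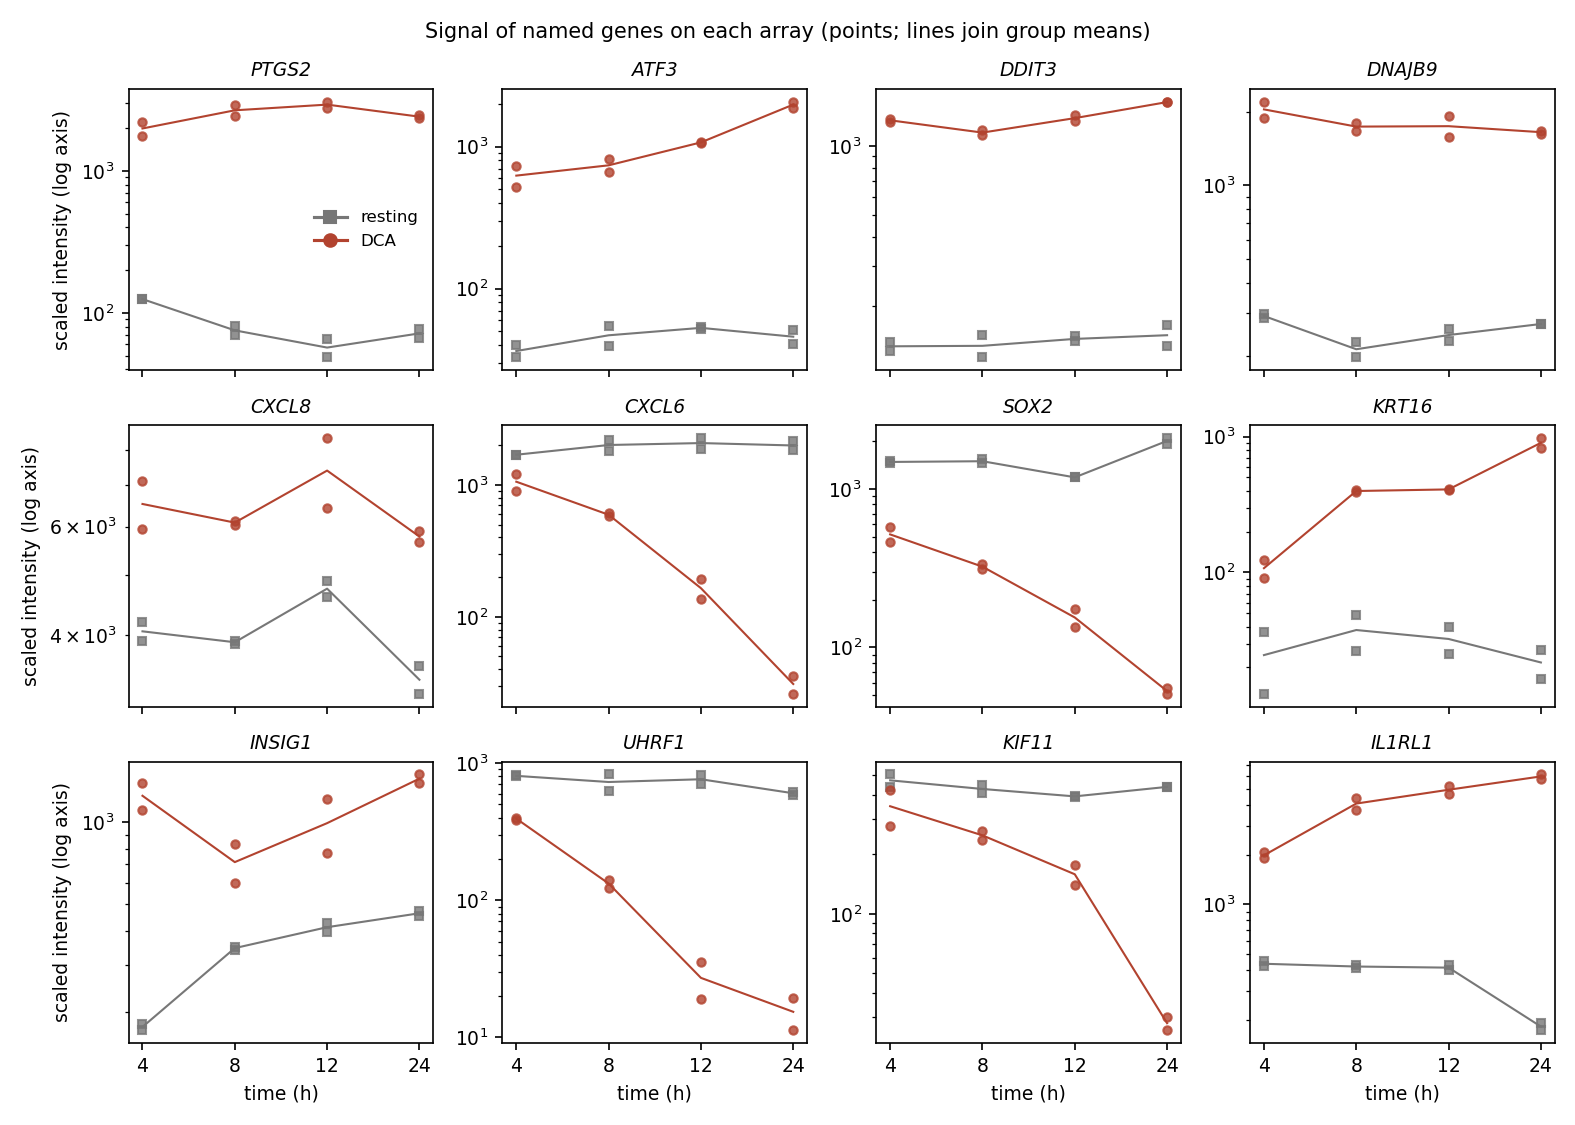
Scaled intensity (arbitrary units, log axis with a range of its own in each panel) of 12 named genes against time in h (evenly spaced categories). Each point is an array, grey squares for resting cells and red circles for DCA, and lines join the means of the 2 arrays of a group, with no overlap of the groups for PTGS2, ATF3, DDIT3 and DNAJB9 at any time.

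RNA quality signs moved with the exposure. The ratio of the 3' to the 5' control probe set of ACTB was 2.16 (SD 0.50, n = 8 arrays) with DCA and 1.63 (SD 0.15, n = 8) in resting cells (two-sided exact permutation p = 0.00777). For GAPDH it was 1.22 (SD 0.10, n = 8) with DCA and 1.06 (SD 0.06, n = 8) in resting cells (two-sided exact permutation p = 0.000777). These 2 ratios were the ones tested, and the test exchanged all arrays without regard to time or group. The same-numbered log2 differences of the ACTB ratio were 0.62 and 0.54 at 4 h and 0.71 and 0.91 at 12 h. They were 0.16 and -0.06 at 8 h and 0.17 and 0.02 at 24 h. Those of GAPDH ran from 0.11 to 0.30 over the times. The ACTB ratio was highest in the DCA arrays of 12 h, at 2.53 and 3.05, and the falls of the S phase and mitosis genes and the rises of the stress genes given above come from the same arrays.

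**Figure D3:**
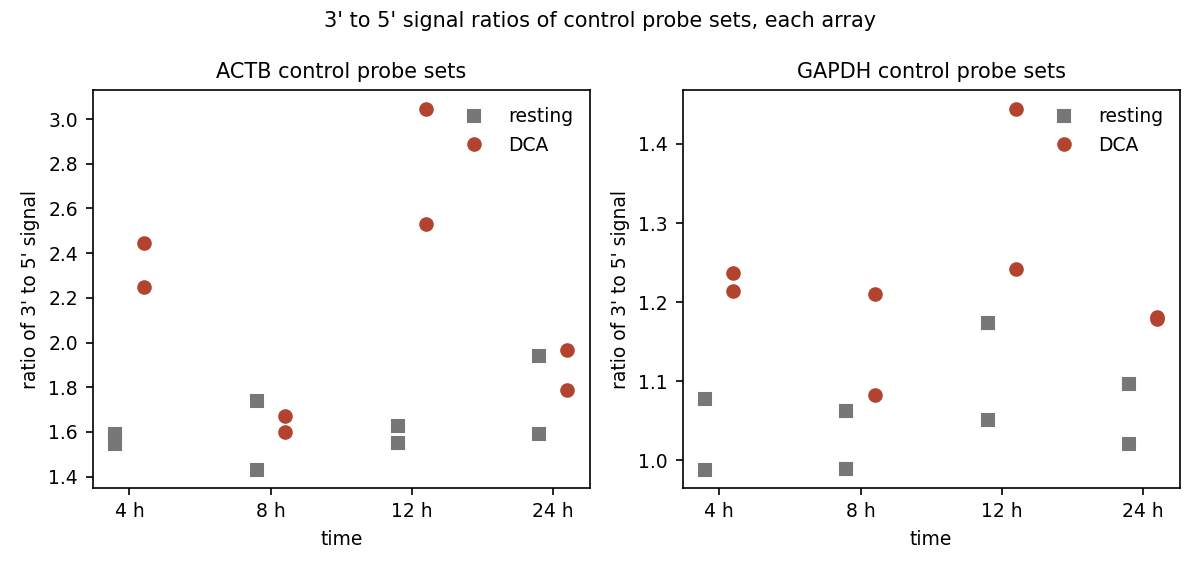
Ratio of the 3' to the 5' control probe set (no unit) of ACTB and GAPDH on each array against time in h (evenly spaced categories), with each point an array, grey for resting cells and red for DCA. The ACTB ratio ran from 1.43 to 1.94 in resting cells and from 1.60 to 3.05 with DCA.

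At 4 h, the earliest time, the 6 largest rises included immediate early and ATF4 list genes. EGR1 rose by 4.43 (SE 0.25, n = 2 arrays per side, limma adjusted p = 6.32e-09), ATF3 by 3.95 (SE 0.19), PTGS2 by 3.94 (SE 0.15) and DUSP1 by 3.79 (SE 0.17). CHAC1 (3.77, SE 0.18) and HBEGF (3.28, SE 0.17) came next. The largest falls were the transcription factor ZIC1 (-3.19, SE 0.69), the glycosyltransferase B3GALT5 (-3.17, SE 0.43), the arginine methyltransferase PRMT7 (-2.94, SE 0.57), RBM4B (-2.87, SE 0.35), LFNG (-2.85, SE 0.57) and CEBPA (-2.76, SE 0.50). The DCA signals of ZIC1, B3GALT5, PRMT7 and CEBPA were below that limit. ZIC1 (adjusted p = 0.00454) and LFNG lost their calls with the mean of all probe sets (-0.84 and -1.54), and ZIC1 lost its call without the first resting array of 4 h (-2.91).

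As lists at 4 h, the ATF4 list (22 of 30 rose, 1 fell, median 1.13, camera adjusted p = 2.32e-28), immediate early genes (14 of 19 rose, 1 fell, median 1.24), NF-κB genes (14 of 24 rose, 0 fell, median 0.74) and EGFR and ERK genes (12 of 18 rose, 0 fell, median 0.74) were called up. The YAP and SRF list was called up at this time, with 6 of 15 rising and 0 falling (median 0.13, adjusted p = 6.43e-06). Its matricellular members CCN2 (2.83, SE 0.27) and CCN1 (2.79, SE 0.18) led it, with AMOTL2 at 2.35 (SE 0.20). Sterol genes rose in 9 of 19 cases (median 0.48, adjusted p = 9.34e-10), with INSIG1 at 2.78 (SE 0.18). Hypoxia genes were called up as well, with 5 of 21 rising and 2 falling (median 0.28, adjusted p = 0.000605), as were tRNA synthetases (8 of 17 rose, median 0.29) and metallothioneins (3 of 7 rose, median 0.36). S phase genes already fell in 16 of 26 cases (median -0.48, adjusted p = 1.14e-07). All of these calls held with an estimated correlation, and those of ER chaperones, fatty acid, FOXO, ribosome biogenesis, ribosomal protein, EMT, mitosis and interferon genes did not (adjusted p = 0.0887, 0.133, 0.352, 0.315, 0.359, 0.0887, 0.0744 and 0.0913 with an estimated correlation).

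In total 2269 genes were called at 4 h, 892 higher and 1377 lower, with 264 and 401 of them changed at least 2-fold. The share of higher genes was 39.31%, and 68.54% with median centring. The count was 1244 without the first resting array of 4 h and 1129 without the second, and 1369 with the mean of all probe sets.

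At 8 h the ATF4, ER chaperone and S phase medians lay further from 0 than at 4 h, a difference that was not tested between these 2 times. PTGS2 rose by 5.07 (SE 0.15, n = 2 per side, limma adjusted p = 3.77e-12), ESM1 by 4.33 (SE 0.27), C11orf96 by 3.89 (SE 0.54), ATF3 by 3.88 (SE 0.19), CHAC1 by 3.83 (SE 0.18) and DUSP1 by 3.75 (SE 0.17). Falls were led by the divergent transcript BAIAP2-DT (-4.24, SE 0.39), the lipid kinase PIK3C2B (-4.05, SE 0.29), ZNF488 (-3.99, SE 0.39), SMAD6 (-3.47, SE 0.47), ASB2 (-3.34, SE 0.59) and the BMP-responsive ID3 (-3.28, SE 0.21), and the DCA signals of BAIAP2-DT, ZNF488, SMAD6 and ASB2 were below the limit. ER chaperones rose in 19 of 24 cases and fell in 1 (median 0.60, camera adjusted p = 1.77e-13), and HYOU1 was at 1.15 (SE 0.11) after 0.17 (SE 0.11) at 4 h. The ATF4 list had 25 of 30 rising and 0 falling (median 1.95, adjusted p = 7.65e-32). NRF2 targets rose in 8 of 21 cases and fell in 1 (median 0.31, adjusted p = 5.37e-07), with HMOX1 at 2.57 (SE 0.18), and autophagy genes rose in 9 of 22 and fell in 1 (median 0.15, adjusted p = 9.96e-05). S phase genes fell in 23 of 26 cases, while CDC6 alone of them rose (0.56, SE 0.16; median -1.18, adjusted p = 2.61e-15). Interferon genes fell in 9 of 18 cases and rose in 1 (median -0.58, adjusted p = 0.0046).

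Also called up at 8 h were immediate early (13 of 19 rose), EGFR and ERK (12 of 18 rose, 1 fell), NF-κB (13 of 24 rose, 4 fell), tRNA synthetase (10 of 17 rose, 2 fell), sterol (8 of 19 rose, 1 fell), hypoxia (6 of 21 rose, 3 fell) and metallothionein genes (3 of 7 rose). Calls of fatty acid, FOXO, ribosomal protein, EMT, mitosis and respiratory chain genes were lost with an estimated correlation (adjusted p = 0.0762, 0.369, 0.387, 0.0606, 0.0646 and 0.186 with an estimated correlation). Of the 4060 genes called, 1499 were higher and 2561 lower, 466 and 876 of them by at least 2-fold, and the share of higher genes was 36.92%, or 61.0% with median centring.

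At 12 h PTGS2 reached its highest measured change, 5.60 (SE 0.15, n = 2 per side, limma adjusted p = 7.97e-13), and S phase genes were lower throughout. C11orf96 rose by 5.10 (SE 0.54), the peptide hormone gene SPX by 4.68 (SE 0.44), DUSP1 by 4.40 (SE 0.17), the kinesin KIF21B by 4.29 (SE 0.50) and ATF3 by 4.24 (SE 0.19). The largest falls were LFNG (-4.99, SE 0.57), UHRF1 (-4.67, SE 0.22), ZNF488 (-4.42, SE 0.39), RERG (-4.21, SE 0.37), ITGB8 (-4.01, SE 0.33) and CXCL6 (-3.64, SE 0.18). The resting signals of C11orf96, SPX and KIF21B and the DCA signals of LFNG, ZNF488 and RERG were below the limit. ITGB8 lost its call with the mean of all probe sets (-0.84). All 26 S phase genes fell (median -1.88, camera adjusted p = 7.24e-21), and 17 of 23 mitosis genes fell with 0 rising (median -0.64, adjusted p = 6.65e-07). The ATF4 list had 25 of 30 rising and 0 falling (median 2.07), tRNA synthetases 10 of 17 rising and 2 falling (median 0.96), NRF2 targets 12 of 21 rising and 1 falling (median 0.42) and metallothioneins all 7 rising (median 0.59, adjusted p = 6.23e-05). These arrays had the highest ACTB 3' to 5' ratios.

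ER chaperones (17 of 24 rose, 1 fell), immediate early (14 of 19 rose, 1 fell), EGFR and ERK (12 of 18 rose, 1 fell), NF-κB (13 of 24 rose, 4 fell), sterol (10 of 19 rose, 2 fell) and autophagy genes (10 of 22 rose, 1 fell) were also called up at 12 h, and interferon genes down (9 of 18 fell, 1 rose). Calls of FOXO, ribosomal protein, EMT, ribosome biogenesis and respiratory chain genes were lost with an estimated correlation (adjusted p = 0.243, 0.396, 0.0787, 0.174 and 0.0838 with an estimated correlation). Of the 4965 genes called, 1985 were higher and 2980 lower, 709 and 1213 of them by at least 2-fold. The share of higher genes was 39.98%, and 55.9% with median centring.

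At 24 h the most genes of any time were called, and the S phase and mitosis lists had fallen. C11orf96 rose by 5.43 (SE 0.54, n = 2 per side), ATF3 by 5.32 (SE 0.19), the IL-13 decoy receptor IL13RA2 by 5.23 (SE 0.16, limma adjusted p = 7.2e-13), KRT16 by 5.16 (SE 0.35), IL1RL1 by 5.01 (SE 0.10) and PTGS2 by 4.99 (SE 0.15). Falls were led by CXCL6 (-5.84, SE 0.18, adjusted p = 7.2e-13), LFNG (-5.79, SE 0.57), SOX2 (-5.14, SE 0.13), CDH5 (-5.13, SE 0.29), UHRF1 (-5.005, SE 0.22) and ITGB8 (-4.99, SE 0.33). The DCA signals of LFNG and CDH5 and the resting signal of C11orf96 were below the limit, and the DCA arrays of UHRF1, at 11.3 and 19.4 units, lay on both sides of it. All 23 mitosis genes fell (median -2.34, camera adjusted p = 9.82e-20), with KIF11 at -3.79 (SE 0.17), and 25 of 26 S phase genes fell with 0 rising (median -2.62, adjusted p = 1.11e-20), with TYMS at -4.09 (SE 0.10). The ATF4 list had 26 of 30 rising and 0 falling (median 2.09, adjusted p = 1e-21). Autophagy genes rose in 12 of 22 cases and fell in 1 (median 0.50, adjusted p = 4.81e-05), and respiratory chain genes fell in 17 of 24 cases with 0 rising (median -0.50, adjusted p = 4.81e-05, and adjusted p = 0.0436 with an estimated correlation).

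Other lists called up at 24 h were immediate early (14 of 19 rose, 0 fell, median 1.85), EGFR and ERK (12 of 18 rose, 2 fell, median 1.40), tRNA synthetase (12 of 17 rose, 4 fell, median 1.08), NF-κB (11 of 24 rose, 3 fell, median 0.79), sterol (11 of 19 rose, 3 fell, median 0.73) and NRF2 genes (13 of 21 rose, 1 fell, median 0.41), and interferon genes were called down (9 of 18 fell, 3 rose, median -0.87). ER chaperones now rose in 11 of 24 cases and fell in 4 (median 0.39, camera adjusted p = 0.00454, and adjusted p = 0.202 with an estimated correlation), with CALR at -0.62 (SE 0.10). YAP and SRF targets fell in 9 of 15 cases and rose in 3 (median -0.88, adjusted p = 0.0153, and adjusted p = 0.178 with an estimated correlation), and FOXO and ribosome biogenesis calls were likewise lost (adjusted p = 0.181 and 0.252 with an estimated correlation). Of the 6002 genes called, 2535 were higher and 3467 lower, 1049 and 1879 of them by at least 2-fold. The share of higher genes was 42.24%, and 56.35% with median centring.

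**Figure D4:**
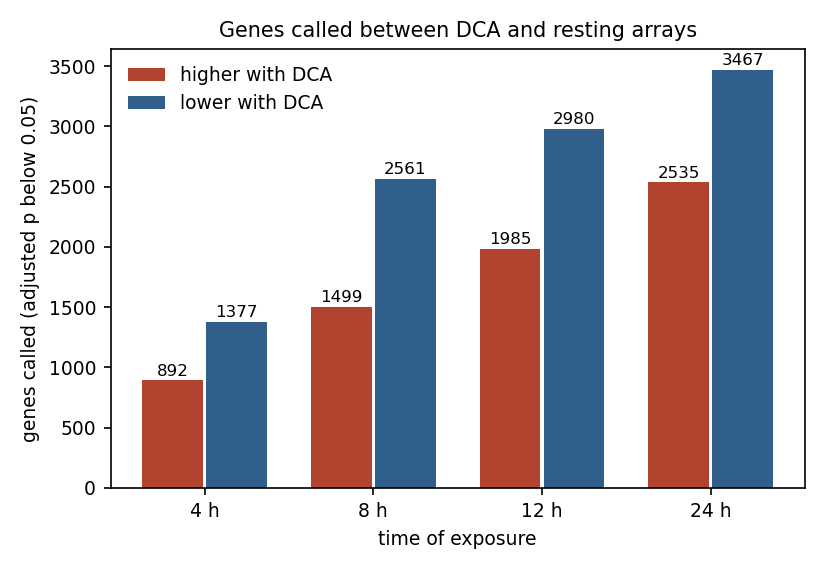
Number of genes called by limma (adjusted p below 0.05) between DCA and resting arrays against time of exposure in h (evenly spaced categories), with red bars for genes higher and blue bars for genes lower with DCA, 2 arrays per group. The counts were 892 higher and 1377 lower at 4 h and 2535 higher and 3467 lower at 24 h.

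Across the times, 557 genes were called higher and 593 lower at all 4, and 7908 were called at 1 or more. Of the 892 genes higher at 4 h, 642 were also higher at 24 h, where independent lists would share 155.8. Of the 1377 lower at 4 h, 782 were also lower at 24 h, where independent lists would share 329.0. These times used different arrays but shared each gene's estimate of the spread. Independent lists are therefore not a full baseline, and some sharing above it is built in. Another 64 genes were higher at 4 h and lower at 24 h, 135 went the other way, and 288 were called in opposite directions at some pair of times.

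The test of whether the DCA effect differed between times asked for which genes the difference between DCA and resting cells grew or shrank. Such a change can come from the DCA cells or from the resting cells. Genes such as IL13RA2 and KRT16 had a larger rise at 24 h, and genes such as CXCL6, CCN2 and CDH5 a lower effect. IL13RA2 had a change of 0.30 (SE 0.16) at 4 h and 5.23 (SE 0.16) at 24 h, a difference of 4.93 (SE 0.23, limma F test adjusted p = 7.55e-09). Differences for LOC728392 (4.99, SE 0.99), SUN3 (4.68, SE 0.77), OSCAR (4.25, SE 0.77), APBB1IP (4.24, SE 0.77) and KIF21B (3.79, SE 0.71) had larger errors, and APBB1IP lost its call with the mean of all probe sets (1.93). CXCL6 went from -0.69 (SE 0.18) to -5.84 (SE 0.18), a difference of -5.15 (SE 0.25, F test adjusted p = 1.15e-08). CCN2, a YAP target, had an effect that turned: it rose by 2.83 at 4 h and 0.83 at 8 h, and fell by 1.53 at 12 h and 2.21 at 24 h (SE 0.27 each), a difference of -5.04 (SE 0.38). CDH5 (-4.70, SE 0.41), the kinase GASK1B (-4.58, SE 0.33), the growth factor receptor FGFR3 (-4.53, SE 0.62) and TSPAN1 (-4.44, SE 0.52) completed the set. LOC728392, SUN3, APBB1IP, KIF21B, CDH5 and GASK1B had groups below the low-value limit, so the sizes of their differences are uncertain. SUN3 and KIF21B lay below it in the resting and the DCA cells of 4 h alike. In all 3271 genes were called, 1553 with a higher and 1718 with a lower effect at 24 h, and 1910 with the mean of all probe sets.

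For lists the contrast was the DCA effect at 24 h minus that at 4 h. Mitosis genes declined in 22 of 23 cases with 0 rising (23 adjusted over the list alone, median difference -2.09, camera adjusted p = 1.18e-24), beside S phase genes in 23 of 26 (25 adjusted over the list alone, median -2.12, adjusted p = 2.4e-23). YAP and SRF targets declined in 12 of 15 cases and increased in 1 (the same adjusted over the list alone, median -1.52, adjusted p = 3.06e-08). The ATF4 list increased in 15 of 30 cases and declined in 1 (17 and 1 adjusted over the list alone, median 0.66, adjusted p = 6.71e-08), and autophagy genes increased in 11 of 22 with 0 declining (13 and 1 adjusted over the list alone, median 0.68, adjusted p = 2.81e-05). These 5 calls held with an estimated correlation. Those of NRF2 (median 0.57), tRNA synthetase (0.51), immediate early (0.49), heat shock (-0.54), ribosome biogenesis (-0.62) and respiratory chain genes (-0.49) did not (adjusted p = 0.0561, 0.0653, 0.175, 0.123, 0.123 and 0.0684 with an estimated correlation).

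The resting cells changed over the same hours, which gives the background for each comparison. From 4 to 24 h the sterol synthesis and hypoxia lists rose in them, and the NF-κB list fell. CYP1B1 and CYP1A1, cytochromes induced by the aryl hydrocarbon receptor, fell by 2.92 (SE 0.17, n = 2 arrays per side, limma F test adjusted p = 1.13e-07) and 2.82 (SE 0.28). CDC25A (-2.48, SE 0.51), SIPA1L2 (-2.25, SE 0.23), GPAT3 (-1.99, SE 0.11) and CRISPLD2 (-1.97, SE 0.28) also fell. MIR4300HG rose by 2.41 (SE 0.44), the glycolytic ALDOC by 1.999 (SE 0.17), TP53INP1 by 1.97 (SE 0.23), TSPAN1 by 1.95 (SE 0.37), the sodium channel subunit SCNN1A by 1.86 (SE 0.31) and CDH5 by 1.85 (SE 0.29). MIR4300HG at 4 h and CDC25A at 24 h were below the low-value limit. TP53INP1, SCNN1A, CDC25A, SIPA1L2 and CRISPLD2 lost their calls with the mean of all probe sets. CDC25A, TSPAN1, SCNN1A and CDH5 lost theirs without either resting array of 24 h. So did CDC25A without any of those of 4 and 12 h, SCNN1A without either of 4 h, TSPAN1 and MIR4300HG without the first of 4 h, and CRISPLD2 without the first of 24 h. TSPAN1 and SCNN1A also lost theirs without the intensity trend. With 1 array left out the changes stayed between -2.69 and -2.28 for CDC25A, 1.76 and 2.13 for TSPAN1, 1.81 and 1.91 for SCNN1A, 1.82 and 1.87 for CDH5, 2.22 and 2.60 for MIR4300HG, and -2.27 and -1.66 for CRISPLD2.

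Between 4 and 24 h in the resting cells, 16 of 19 sterol genes rose and 0 fell (18 rose adjusted over the list alone, median 0.96, camera adjusted p = 1.9e-25), with MSMO1 at 1.64 (SE 0.16) and SQLE at 1.40 (SE 0.09). Of 21 hypoxia genes 11 rose and 0 fell (14 adjusted over the list alone, median 0.55, adjusted p = 2.41e-13), with EGLN3 at 1.40 (SE 0.17). NF-κB genes fell in 8 of 24 cases with 0 rising (9 adjusted over the list alone, median -0.30, adjusted p = 1.6e-11), with IL1B at -1.23 (SE 0.13). Called up too were FOXO (6 of 19 rose, 10 adjusted over the list alone, median 0.56), fatty acid (3 of 13, 5 adjusted over the list alone, median 0.54) and p53 genes (3 of 20, the same adjusted over the list alone, median 0.18), all with 0 falling. Mitosis (6 of 23 fell, median -0.28), S phase (3 of 26, median -0.20), ribosome biogenesis (3 of 20, median -0.37) and tRNA synthetase genes (2 of 17, median -0.20) were called down with 0 rising (6, 3, 8 and 4 fell adjusted over the lists alone). ER chaperones rose in 7 of 24 cases (10 adjusted over the list alone, median 0.20, adjusted p = 2.36e-05), a call lost with an estimated correlation (adjusted p = 0.0864 with an estimated correlation), and the others held. In all 448 genes were called, 249 higher and 199 lower at 24 h. That count was 209 with the mean of all probe sets and 140 without the intensity trend, 175 without either resting array of 4 h, and 116 and 122 without the first and the second resting array of 24 h. Among the called genes 55.58% were higher, and 40.98% with median centring.

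TRIB3, an inhibitor of AKT that is induced through ATF4 and CHOP, and CXCL8, which encodes interleukin 8, were examined in every comparison. Another TRIB3 probe set, with 1.2 to 13.5 units, was too dim to be tested. The one tested was also dim, with 3.2 to 30.9 units over the 16 arrays. Its DCA change was 1.37 at 4 h (SE 0.63, limma adjusted p = 0.166), 1.08 at 8 h (adjusted p = 0.234), -0.87 at 12 h (adjusted p = 0.327) and -0.07 at 24 h (adjusted p = 0.945), and 0.38 in the mean (SE 0.31, adjusted p = 0.352), with 0.15 to 0.60 when 1 array was left out. Its effect did not pass the test of a difference between times (-1.45, SE 0.89, adjusted p = 0.206), nor did resting cells over time (1.64, SE 0.63, adjusted p = 0.293). The test of a difference between times passed without the first DCA array of 12 h (-1.45, adjusted p = 0.0392, against 0.0392 to 0.491 over the alternatives). The mean passed without the 12 h arrays (0.79, adjusted p = 0.036, against 0.036 to 0.699 over the alternatives). CXCL8 was among the brightest genes and rose at each time, by 0.68 (SE 0.12, adjusted p = 0.000942), 0.64 (adjusted p = 0.000749), 0.63 (adjusted p = 0.000687) and 0.77 (adjusted p = 6.42e-05), with a mean of 0.68 (SE 0.06, adjusted p = 6.6e-08). The call at 12 h was lost with quantile normalization (0.19, adjusted p = 0.123). Neither its effect over time (0.09, SE 0.17, adjusted p = 0.905) nor resting cells over time (-0.26, SE 0.12, adjusted p = 0.142) passed with this probe set. The second, dimmer probe set of CXCL8 rose by 0.87, 1.27, 0.72 and 1.73 at the 4 times, and by 1.15 in the mean (SE 0.06, adjusted p = 2.12e-10). With it both F tests passed: the DCA effect was higher at 24 h than at 4 h by 0.86 (SE 0.18, adjusted p = 0.00293), and the signal of resting cells fell by 0.86 (SE 0.13, adjusted p = 0.000876).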

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

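The tests of brightness, RNA integrity, serum and a rise in the resting cells were chosen after the results were seen, and the tests of other splits and of compression before. For 103 of the 154 genes named in a DCA comparison and for 11 of the 30 lists, the effect of DCA differed between the times, by the limma F test for genes and the camera test of the 24 h minus 4 h contrast for lists. Of these 11 lists, 5 were called with an estimated correlation as well. Over all genes the F test called 3271 of 14509 (22.54%). The named genes were chosen from these same data, some of them by this F test, so a higher share among them was built in. Each value below is the DCA effect at 24 h minus that at 4 h on the log2 scale.

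Differences of 1 or more towards higher expression were those of LOC728392 4.99, IL13RA2 4.93, SUN3 4.68, OSCAR 4.25, APBB1IP 4.24, KIF21B 3.79, KRT16 3.08, SPX 3.02, IL1RL1 2.83, OCLN 2.66, ULK1 2.37, SRXN1 2.28, WIPI1 2.21, HMOX1 2.01, RBM4B 1.82, SLC7A11 1.82, SLC30A1 1.79, MMP1 1.64, NDRG1 1.54, PLK3 1.54, ESM1 1.53, WARS1 1.505, IL1B 1.49, IL11 1.44, ATF3 1.37, ACSS2 1.29, B3GALT5 1.19, ZEB1 1.16, DUSP5 1.14, DUSP1 1.07, PTGS2 1.05. For RBM4B and B3GALT5 this was a fall with DCA that became smaller. A part of some differences came from the resting cells. The resting signal of PTGS2 fell from 126 and 125 units at 4 h to 67 and 77 at 24 h. Its DCA signal went from 2200 and 1772 units to 2342 and 2467. For IL1RL1 the resting signal fell from 422 and 452 units to 173 and 191, and the DCA signal rose from 2068 and 1902 to 6144 and 5798. The resting signal of ATF3 did not fall, with 40 and 33 units at 4 h and 51 and 41 at 24 h. Smaller positive differences were those of IL1A 0.86, MAP1LC3B 0.85, SEC24D 0.82, ETV5 0.75, YARS1 0.71, GARS1 0.71, DUSP6 0.69, GABARAPL1 0.67, NDUFV1 0.28, HERPUD1 0.023.

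Differences of 2 or more towards lower expression, outside the cell cycle genes, were those of IFIT3 -2.00, TNFSF10 -2.17, CAVIN2 -2.20, MYL9 -2.24, THBS1 -2.35, KRT13 -2.58, AKR1B10 -2.64, EGLN3 -2.74, CYP24A1 -2.86, LFNG -2.94, IFIT2 -3.04, ID3 -3.12, CORO1A -3.13, SMAD6 -3.35, SOX2 -3.62, RERG -3.69, DKK1 -3.73, ITGB8 -3.77, TSPAN1 -4.44, FGFR3 -4.53, GASK1B -4.58, CDH5 -4.70, CCN2 -5.04, CXCL6 -5.15. Smaller negative differences were those of MYC -0.068, CCND1 -0.50, GDF15 -0.68, NOP16 -0.70, MSMO1 -0.71, ZNRF3 -0.71, PIK3C2B -0.73, LATS2 -0.81, NDUFA8 -0.81, AMOTL2 -1.04, NHP2 -1.04, POLR1B -1.09, LAPTM5 -1.10, NDUFB8 -1.10, HBEGF -1.11, ABCC4 -1.14, INSIG1 -1.15, COL1A1 -1.23, DDB2 -1.32, BAIAP2-DT -1.42, PMAIP1 -1.47, OAS1 -1.56, EGR1 -1.57, S100A2 -1.72, IFIT1 -1.74, MMP7 -1.75, HSPE1 -1.76, TM7SF2 -1.84, COL1A2 -1.85. For some of these genes the rise over resting cells became smaller and did not turn, as for INSIG1, HBEGF and EGR1. For INSIG1 the signal of the DCA cells did not fall, with 1396 and 1106 units at 4 h and 1393 and 1499 at 24 h. Its resting signal rose from 172 and 182 to 472 and 454 units.

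Among the cell cycle genes the differences were BUB1B -1.78, CCNE2 -2.15, FOXM1 -2.21, BIRC5 -2.53, KIF20A -2.82, GINS1 -3.04, KIF11 -3.33, MCM10 -3.47, UHRF1 -3.98. Of the lists, mitosis moved by -2.09, S phase by -2.12, YAP and SRF targets by -1.52, ribosome biogenesis by -0.62, heat shock by -0.54 and the respiratory chain by -0.49. Autophagy moved by 0.68, ATF4 by 0.66, NRF2 by 0.57, tRNA synthetases by 0.51 and immediate early genes by 0.49. With an estimated correlation the calls of mitosis, S phase, YAP and SRF, ATF4 and autophagy genes held. Those of ribosome biogenesis, heat shock, respiratory chain, NRF2, tRNA synthetase and immediate early genes were lost (adjusted p = 0.123, 0.123, 0.0684, 0.0561, 0.0653 and 0.175 with an estimated correlation).

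The first pattern weighed was the number of genes called between DCA and resting arrays. With time in the model, the real split of the 16 arrays called 6645 genes, and the highest of the other splits drawn called 2974. Of 100 splits, 1 (the real one) called as many, which is the smallest share they can give. The splits treat all arrays as separate, which the labels do not state. On that assumption, chance alone is argued against as the cause. Different brightness of the deposited arrays is argued against as the whole cause of the calls at 24 h. With only the arrays of 12 and 24 h, all deposited on a common scale, 5897 genes were called at 24 h. The arrays off that scale were all from 4 and 8 h. The count at 24 h therefore does not bear on the calls at those times, where brightness stays open as a cause. Lower RNA integrity is argued against as the whole cause as well: the ACTB ratio difference was largest at 12 h, yet the median change of called genes was higher at 24 h, by 0.146 or more between any of the same-numbered differences of these times. DCA itself and the absence of serum in its medium stay open as causes of the calls.

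The second pattern was the fall of the S phase and mitosis lists. A rise in the resting cells is argued against as its cause, because the median of the 49 genes changed from 4 to 24 h by -2.37 and -2.34 in the DCA arrays, and by -0.26 and -0.18 in the resting ones. A loss of serum may lower the same genes, and the median of both lists at 24 h, -2.45, is what either cause predicts. The design holds no culture without both DCA and serum that the labels identify, so these cannot be told apart.

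The third pattern was the smaller rise of the brighter CXCL8 probe set (0.68 against 1.15). Compression of changes in very bright probe sets could give it. Among genes with a probe set in the top 1% of signal, the dimmer probe set changed more in 57.3% of 96, against 54.1% of 1244 genes at the 80th to 95th percentile (two-sided Fisher exact p = 0.595). Compression and a difference between the transcripts that the probe sets detect cannot be told apart with these shares.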

How the results depend on the processing

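The pseudocount of 32 and the fits of only 12 and 24 h, only 4 and 8 h, or all times but 12 h were chosen after seeing the data, and the other alternatives before. Of 6284 values of 219 gene results under an alternative, 6165 kept their direction and their side of the threshold, and of 898 values of 30 lists 846 did. In 37 gene results and 14 lists at least 1 alternative changed this. Where a sentence below gives no cause, the cause was not tested.

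Leaving out 1 array at a time gave 1129 to 2636 genes called at 4 h, 2785 to 4405 at 8 h, 3733 to 5131 at 12 h, 4704 to 6306 at 24 h, 7016 to 7603 in the mean of the times, 2359 to 3885 for the change of the effect over time, and 116 to 542 for resting cells. Lists called in the mean numbered 17 to 19. An arm left with 1 array is assumed to vary like the other groups. The count at 4 h fell to 1244 without the first and 1129 without the second resting array of 4 h. That of resting cells fell to 175 without either resting array of 4 h, and to 116 and 122 without those of 24 h, where fewer arrays entered the test.

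With the mean of all probe sets of a gene, 1369 genes were called at 4 h, 1910 for the change over time and 209 for resting cells, and without the intensity trend 140 for resting cells. The other counts stayed within 1.5 times those reported. Under all alternatives but single arrays left out, the counts ran from 1369 to 2868 at 4 h, 2724 to 4636 at 8 h, 3649 to 5449 at 12 h, 4669 to 7151 at 24 h, 6209 to 7899 in the mean, 1910 to 3939 for the change over time and 140 to 636 for resting cells, with 13 to 19 lists called. The lowest number of lists came with an estimated correlation. With each time fitted alone, and so with a spread of its own, 1625, 3489, 3684 and 7151 genes were called at 4, 8, 12 and 24 h.

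TRIB3 at 24 h, not called, turned to 0.074 with quantile normalization, 0.12 with median centring and 0.0074 with the mean of all probe sets, and ran from -0.29 to 0.14 with 1 array left out. TRIB3 at 12 h ran from -1.79 to 0.042 in the same way. TRIB3 and MUC6 in the mean were -0.47 and -0.24 with only the arrays of 12 and 24 h. The CXCL8 difference between times ran from -0.038 to 0.22 with 1 array left out. TRIB3 passed in the mean without the 12 h arrays (0.79, adjusted p = 0.036) and in the difference between times without the first DCA array of 12 h (-1.45, adjusted p = 0.0392), and CXCL8 in resting cells with quantile normalization (-0.34) and the mean of all probe sets (-0.56).

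None of the lists whose median turned was called. With median centring, which moves all genes up, the medians were 0.11 for heat shock, 0.057 for p53, 0.041 for YAP and SRF targets, 0.16 for hypoxia, 0.022 for WNT targets and 0.12 for leukocyte markers. Hypoxia was 0.042 with quantile normalization, 0.026 without a filter and 0.020 without the 12 h arrays, heat shock 0.016 and squamous markers -0.41 with the filter at the 60th percentile, p53 0.034 with only 12 and 24 h, and squamous markers -0.045 without the 12 h arrays. With 1 array left out, squamous markers ran from -0.11 to 0.15, hypoxia from -0.068 to 0.021 and leukocyte markers from -0.19 to 0.040.

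For the lists whose call changed, the adjusted p over the alternatives ran from 0.0282 to 0.185 for fatty acid genes, 0.0373 to 0.298 for intestinal markers, 0.00216 to 0.302 for FOXO targets, 0.00493 to 0.408 for ribosome biogenesis, 1.19e-06 to 0.898 for ribosomal proteins, 1.53e-07 to 0.0814 for the respiratory chain and 0.00553 to 0.124 for EMT genes. For CXCL8 at 12 h it ran from 4.41e-05 to 0.123.

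The correlations of same-numbered arrays between DCA and resting cells were 0.12, 0.22, 0.23 and -0.01 at the 4 times. Among all 6 groups of 4, 8 and 12 h they ran from 0.1217 to 0.26, and the second component was lower in array 2 than in array 1 of each, so arrays with the same number deviated together there. Those involving 24 h ran from -0.01 to 0.048. The labels do not say that a number marks a shared experiment, so this is a hint from the data and the fit reported has no block. With the replicate number as a block, 2743, 4548, 5369 and 6381 genes were called at the 4 times and 7801 in the mean. Of the lists, intestinal markers were called with the block (adjusted p = 0.0477) and EMT genes were not (adjusted p = 0.0525). The block changed no other list call and no call of a named gene. Arrays have no depth, and signal over background was not compared with the number of arrays as a limit. The SE in the mean was 0.31 for TRIB3, at the 47th percentile of probe sets, and 0.06 for the much brighter CXCL8.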

Other observations

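CYP1A1, CYP1B1, ID3, SMAD6 and UHRF1 were named by the rule that chose names. The other genes in this part lie outside it and were chosen after their values were seen, as were the 2 lists. The tests of those lists were set before their other members were examined. The values that follow are over the mean of the 4 times, and no list of such genes was tested. The matrix protease MMP10 rose by 2.71 (SE 0.06, limma adjusted p = 4.51e-15), from 0.95 at 4 h to 4.40 at 24 h, and the laminin chain LAMB3 by 2.07 (SE 0.05, adjusted p = 9.63e-15). The complement inhibitor CD55 rose by 2.11 (SE 0.06, adjusted p = 5.21e-14). Of the neutral amino acid transporters, 3 were examined and rose, with SLC1A4 at 2.23 (SE 0.07, adjusted p = 2.41e-13), SLC1A5 at 1.80 (SE 0.06, adjusted p = 5.66e-13) and SLC38A2 at 1.13 (SE 0.07, adjusted p = 1.21e-09). The simple epithelial keratins parted, since KRT8 fell by 0.67 (SE 0.05) and KRT18 rose by 0.39 (SE 0.05). DNMT1, the partner of UHRF1 in copying DNA methylation, fell by 0.72 (SE 0.10).

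Lower activity of the aryl hydrocarbon receptor could have caused the fall of CYP1A1 and CYP1B1 in resting cells between 4 and 24 h. The median change of 10 other targets was -0.045 (SD over members 0.62, camera p = 0.179, and p = 0.198 with an estimated correlation), with 1 higher and 2 lower. Members went both ways, so the test did not decide. TIPARP fell in the resting cells by 0.83 (SE 0.09, limma F test adjusted p = 0.000111). With DCA, CYP1A1 rose by 1.69 (SE 0.14) and CYP1B1 by 2.47 (SE 0.08) in the mean of the times. The 10 other targets were higher with DCA as a list, without adjustment over lists (median 0.41, SD over members 0.94, 7 higher and 1 lower, camera p = 0.00168, and p = 0.0112 with an estimated correlation). At 4 h their median was 0.34 (4 higher and 1 lower, camera p = 0.00592, and p = 0.0207 with an estimated correlation). These 2 tests were run after the values were seen and compare DCA with resting cells, so they do not bear on the fall within resting cells.

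Lower BMP signalling could lie behind the falls of ID3 and SMAD6 with DCA, which were -2.78 (SE 0.10) and -2.92 (SE 0.24) in the mean of the times. The median change of 12 other targets was -0.14 (SD over members 1.09, camera p = 0.415, and p = 0.45 with an estimated correlation), with 4 higher and 5 lower, which decides neither way. Among them ID2 fell by 1.96 (SE 0.08) and ID1 by 1.23 (SE 0.05), HEY1 rose by 1.14 (SE 0.12), and SMAD7 had a change of -0.16 that did not pass. The ligand gene BMP4 fell by 2.34 (SE 0.13).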
